A study of Homo sapiens with 2 samples.

How the data were processed

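Gene expression was measured on Affymetrix U133 Plus 2.0 arrays, which carry 54675 probe sets. The labels name the cells as KYSE150, a human esophageal squamous carcinoma cell line. There were 2 arrays. One was hybridised with RNA of cells treated for 48 hours with the compound 91b1 at 9.5 µg/ml, and the other with RNA of cells given DMSO for the same time, per the labels' protocols. RNA was purified on spin columns and labelled with biotin, per the labels' protocols.

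The authors deposited 1 signal intensity per probe set and array, on a linear scale. The submitters' processing notes name MAS5 and the R package affy. Their versions and settings are not given in the sources used here. MAS5 is designed to subtract a local background, combine the perfect match and mismatch probes of a probe set, and multiply each array by 1 factor. The deposited values bear out that scaling, since the mean without the lowest and highest 2% of probe sets was 500.1 on both arrays. MAS5 gives a detection call per probe set as part of its standard output. Such calls were not used here, so a floor had to be set from the values. The medians of the 2 arrays were 56.5 (DMSO) and 50.5 (91b1), and all values were above 0.

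Of the 54675 probe sets, 41097 were paired with exactly 1 gene symbol by the platform annotation of 2016, 1801 with several, 11721 with none listed, and 62 were array controls, 6 of them with 1 symbol. GAPDH was represented in its lists by a 5' control probe set. Of the 1-symbol probe sets, 41043 had a gene identifier in the RefSeq gene table (assembly GRCh38.p14), and their symbols were the current ones. Some genes are not reported here. Genes on the Y chromosome and XIST (35 in all) were left out of every step. No coordinates were used, because the build behind the probe sets is not named.

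The difference between the arrays was the log2 intensity of the 91b1 array minus that of the DMSO array, with no pseudocount. A floor was set at the 60th percentile of each array's values, 101.5 (DMSO) and 95.3 (91b1). A value under the floor was replaced by the floor, so that a gene above the floor on 1 array only has a lower bound in place of a difference, and a gene under it on both arrays has none. A bound that pointed away from the array above its floor was dropped. Some genes above the floor on 1 array only therefore have neither a difference nor a bound. Among 88 probe sets of genes restricted to other tissues, the 90th percentile was 72.9 (DMSO) and 69.4 (91b1). A gene was represented by its probe set with the highest mean log2 intensity. A gene was counted as different at 2-fold or more.

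With 1 array per group there is no replicate error and no p-value. The differences compare these 2 arrays, and the number of arrays limits their precision. The only error the values hold is technical. It was taken as the SD of the log2 difference between probe sets of the same gene, computed in 6 classes of signal level from 12316 probe sets of genes with at least 2 probe sets above the floor on both arrays. It fell from 0.33 at intensities of 99.7 to 198.6 to 0.17 at 2958 or more. This SD covers the probe sets' disagreement and not the variation between cultures. It is given below as the probe-set SD.

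Gene lists (40 lists with 914 symbols) and the rule for naming genes were fixed before the data were examined. For each list with at least 5 members having a difference or bound, the median log2 difference was taken relative to the median of all genes, and its percentile was found among 10000 random lists of the same size matched on mean log2 intensity in 20 classes. The percentile describes these 2 arrays and ignores that genes of a pathway vary together. The named genes are CCL5, the 12 with the largest difference in each direction among genes above the floor on both arrays whose other such probe sets share the direction, up to 8 lower bounds in each direction, up to 4 members per list with the largest absolute difference, and members needed to show that a list did not move one way. Unnamed loci, antisense genes and genes of unknown reading frame were passed over. A second set of cell lineage lists, the count of list members beyond 2 probe-set SD, the 6 level classes and the top and bottom 2.5% as limits for lists were chosen after seeing the data.

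The 2-fold rule was tested on simulated data, with the probe-set SD as noise and 200 of the genes changed. It recovered 54.5% of genes changed 2-fold, 98% of those changed 3-fold and 99.5% of those changed 4-fold, with 2 to 5 unchanged genes past 2-fold out of about 11011 to 11022. The simulated noise was normal, with no variation between cultures, and probe sets under the floor took the SD of the lowest class. These counts therefore do not say how many of the genes past 2-fold in the data are noise. Of 200 unchanged simulated lists of 20 genes, 3% fell outside the central 95% of the random lists, and of 50 lists shifted by 0.2 on the log2 scale, 94% reached their top 2.5%. Alternatives covered the scaling (median centring, quantile, loess on the mean level), the floor (50th or 75th percentile, or the 90th percentile of the genes restricted to other tissues), an offset equal to the floor, the choice of probe set, and the fold. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.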

Results

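The comparison was of 2 arrays, 1 of cells exposed to 91b1, a derivative of 8-hydroxyquinoline per the series title, and 1 of cells given the solvent DMSO. The labels name the cells as KYSE150, but most squamous genes were under the floor on both arrays, as described below. Each array gave 54675 intensities, and 20740 probe sets were above the floor on both. Over these the log2 intensities of the arrays correlated with Pearson's r = 0.99, across probe sets, which are not independent replicates. Of 19740 named genes, 10628 were above the floor on both arrays, 737 on 1 array only and 8375 on neither. Values below are log2 differences, 91b1 minus DMSO, with the probe-set SD after the ± sign. There was 1 array per group, so none of these differences has a replicate check.

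The comparison asks which transcripts differed after 48 hours of 91b1. Most differences were small, and 95% of the genes with a difference or bound had a value under 1.5-fold. For a gene with a bound only, the fold itself can be larger. At 2-fold or more, 28 genes were higher and 39 lower in the 91b1 array. The higher genes included 2 fibrinogen chains, the epithelial defensin DEFB1 and the protease inhibitor SLPI. The lower ones included CPS1, the mitochondrial enzyme that makes carbamoyl phosphate for the urea cycle, and ACKR3, a scavenging chemokine receptor.

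Among the higher genes above the floor on both arrays, the largest difference belonged to BCHE, the plasma cholinesterase, at 1.58 ± 0.29, from an intensity of 138 to 415. DEFB1 followed at 1.41 ± 0.25, from 334 to 886. The fibrinogen gamma chain FGG went from 1441 to 3653, a difference of 1.34 ± 0.20. The beta chain FGB went from 2081 to 4744, a difference of 1.19 ± 0.17, and its other probe set gave 1.36. DHRS2, a short-chain dehydrogenase, was higher by 1.18 ± 0.22, with 1.41 on its other probe set. HSPA6, an inducible HSP70, was higher by 1.17 ± 0.25, with 1.16 on its other probe set. SLC51B, a subunit of the basolateral bile acid and steroid transporter, was higher by 1.29 ± 0.25. UTS2R, COQ6 (coenzyme Q synthesis), RADIL, GPX3 (secreted glutathione peroxidase) and GEM were higher by 1.35, 1.22, 1.19, 1.14 and 1.11. The other probe set of GPX3 gave only 0.37. SLPI, named through the squamous list, was higher by 1.09 ± 0.20, from 938 to 2000.

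On the lower side, TMEM234 differed by -1.32 ± 0.29. CPS1 went from 2195 to 937, a difference of -1.23 ± 0.20, with -1.02 on its other probe set. ACKR3 went from 1201 to 528, a difference of -1.19 ± 0.22. CHDH, which oxidises choline, gave -1.21 ± 0.29, but -0.40 on another probe set and bounds of -0.53 and 0.52 on 2 more. ZNF696, NPHP4, NFIX, NPTXR, OR7E104P and EBF4 gave -1.17, -1.17, -1.16, -1.14, -1.10 and -1.09, each with no other probe set above the floor on both arrays. A second probe set of NPTXR gave a bound of only -0.26. FAM120B gave -1.11 ± 0.33, with -0.81 on its other probe set. MTOR, the growth-regulating kinase, gave -1.08 ± 0.33 at the low intensities of 284 and 134. Of the genes above the floor in the 91b1 array only, ARHGAP24, a Rac-regulating GTPase activator, was at least 2.76-fold higher and SCARA5 at least 2.39-fold higher. CGAS, PRSS3 and SUFU were at least 2.17-fold, 2.12-fold and 2.10-fold higher. CCBE1, NALCN, TTC38 and NRSN2 were at least 2.90-fold, 2.55-fold, 2.53-fold and 2.36-fold lower, followed by DTWD2, ZNF527, FUT6 and POLL at 2.25-fold to 2.11-fold. The other probe sets of FUT6 went both ways (-0.17, and bounds of 0.04 and 0.60 on the log2 scale).

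**Figure D1:**
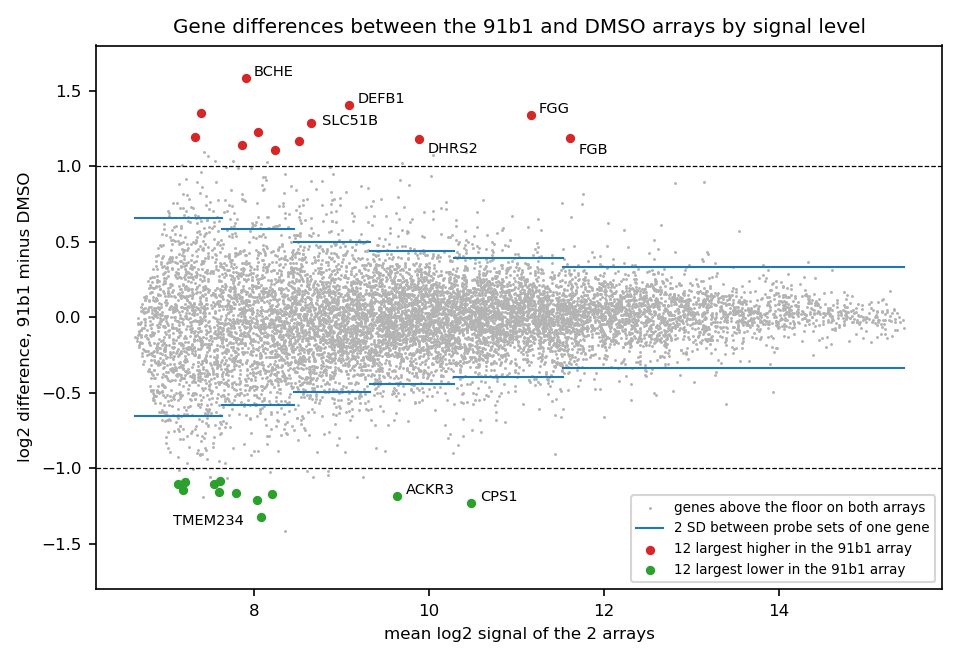
Each grey point is a gene above the floor on both arrays, with its mean log2 signal on the x axis and its log2 difference (91b1 minus DMSO) on the y axis. Blue lines mark 2 probe-set SD, dashed lines 2-fold, and coloured points the 12 named genes with the largest difference in each direction.

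Of the 67 genes at 2-fold or more, 56 rested on a chosen probe set with no other probe set of the gene above the floor on both arrays. For the 48 of them above the floor on both arrays, 10 had other probe sets. There, 10 of 12 other probe sets shared the direction, with a median of 0.61 in that direction. By gene, all other probe sets shared it in 8 of 10 (80%, exact 95% binomial interval 44.4% to 97.48%). The split of higher to lower genes depended on the scaling. It was 67 to 15 after median centring, 37 to 29 after quantile normalization and 38 to 27 after loess. Median centring moved the median of all genes with a difference from -0.01 to 0.16. With the floor at the 75th percentile (353 and 347), 7 genes were higher and 3 lower. These were DEFB1, DHRS2, FGB, FGG, SLPI, TM4SF20 and TM4SF4, and ACKR3, CPS1 and HCFC1. TM4SF20, TM4SF4 and HCFC1 fell outside the naming rule and were chosen after their values were seen.

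CCL5, the T-cell attracting chemokine that the series title names as lower after 91b1, was under the floor on both arrays with each of its 3 probe sets. They read 6.16, 24.5 and 6.80 in the DMSO array and 53.7, 29.2 and 10.3 in the 91b1 array. The floors were 101.5 and 95.3. All of these values lay within the range of genes restricted to other tissues, whose probe sets had 95th percentiles of 87.5 and 104.7, and the highest lay at percentile 86.4 of them. No fold is given for CCL5, and a lower level in the 91b1 array was not seen on any of its probe sets. Of 10 chemokine receptors named on the array, only ACKR3 was above the floor on either array.

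Among the 35 lists with enough members, 6 had medians in the top 2.5% and 6 in the bottom 2.5% of the random lists, against 1.75 expected at both ends together by chance. Lists share members such as ATF3, GDF15 and LCN2, so they are not independent. The 1.75 also takes the genes of a list as varying independently, while genes of a pathway can vary together between any 2 cultures. The excess over it therefore does not show a response to the compound. List medians below are relative to the median gene, and those of these 12 lists kept their direction under all 3 scalings. Over all genes, 3.05% were higher and 3.85% lower by over 2 probe-set SD.

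Genes of the unfolded protein response, the chaperones and folding enzymes of the endoplasmic reticulum, were higher in the 91b1 array. Of 18 members, 16 were above 0, the median was 0.28, and it lay above all 10000 random lists (percentile 100). Without the shared probe sets, 13 members were left, the median was 0.17 and the percentile 99.6. HERPUD1 was higher by 0.63 ± 0.17, DNAJB9 by 0.60 ± 0.20, XBP1 by 0.58 ± 0.20 and PDIA6 by 0.57 ± 0.17. The other probe sets gave 0.48 and 1.19 for DNAJB9, and 0.45, 0.11 and 0.34 for PDIA6. These and HSP90B1 (0.35 ± 0.17, with another of its probe sets in the opposite direction) were the 5 members beyond 2 SD, and none was lower by as much. HSPA5, the main chaperone of that compartment, differed by 0.12 ± 0.17. The ATF4 amino acid response had 20 of 26 members above 0, a median of 0.13 and percentile 99.9. Its members beyond 2 SD were CTH at 0.83 ± 0.25, the stress transcription factor ATF3 at 0.78 ± 0.22, DDIT3 at 0.57 ± 0.22, TRIB3 at 0.35 ± 0.17 and GDF15 at 0.34 ± 0.17, the last with -0.59 on its other probe set. ASNS, a classical target of the pathway, differed by 0.02 ± 0.17.

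Chemokines and interleukins had 14 members above the floor, of which 12 were above 0, with a median of 0.24 and percentile 99.99. IL6 was higher by 0.69 ± 0.29, CXCL1 by 0.54 ± 0.22, CXCL8 by 0.54 ± 0.20 with 1.06 on its other probe set, and IL11 by 0.44 ± 0.20. CCL2, which attracts monocytes, differed by -0.50 ± 0.25 (from 703 to 497). The NF-kappaB target list, which shares regulators with these chemokines, had a median of -0.02 and percentile 38.0 (median 0.0021 where the other probe sets of each gene shared its direction, and -0.10 with percentile 7.81 with the floor at the 75th percentile), with CYLD at -0.78 ± 0.29 (-0.34, 0.39 and -0.58 on its other probe sets), TNFAIP3 at 0.53 ± 0.29 (a bound of -0.18 on another) and TNFAIP2 at -0.35 ± 0.20. Interferon-stimulated genes had a median of 0.04 and percentile 82.1, but 0.23 and 99.8 without the shared probe sets, with IFITM3 at 0.94 ± 0.22, ISG20 at 0.87 ± 0.25 (0.90 on its other probe set) and OAS3 at -0.51 ± 0.25 (-0.41).

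Extracellular matrix genes were lower in the 91b1 array, with 10 of 11 members below 0, a median of -0.33 and percentile 0.01. With all probe sets of a gene averaged the median was -0.16 and the percentile 0.49, and where the other probe sets shared the direction the median was -0.49. THBS1 differed by -0.74 ± 0.20, the collagen chain COL5A1 by -0.56 ± 0.25 and the collagen crosslinking enzyme LOXL2 by -0.51 ± 0.20. Other probe sets gave -0.05, -0.40 and -0.97 for THBS1 and -0.47 and -1.03 for COL5A1. COL6A2 was at least 1.62-fold lower. These were the 4 members beyond 2 SD. Mesenchymal genes had a median of -0.12 and percentile 2.32, led by the transcription factor SNAI2 at -0.90 ± 0.33 and TAGLN at -0.59 ± 0.25 (-0.81 on its other probe set), while VIM differed by -0.13 ± 0.17 and FN1 by 0.02 ± 0.20. That percentile was 3.24 after loess, 4.18 after quantile normalization, 8.97 with the floor at the 75th percentile and 8.69 without the probe sets shared between transcripts. Metalloproteinases and other invasion genes had a median of -0.05 and percentile 9.72. It was 2.44 with the floor at the 50th percentile, 2.37 with the floor from genes restricted to other tissues, and 37.6 with the floor at the 75th percentile, where the median was 0.0033. MMP2 differed by -0.90 ± 0.33 at the low intensities of 228 and 122, MMP15 by -0.65 ± 0.33, and MMP7 by 0.42 ± 0.22. Epithelial junction genes had a median of 0.11 and percentile 92.2, but 0.01 and 47.3 without the shared probe sets and 0.04 and 69.1 with the floor at the 75th percentile, with CDH1 at 0.24 ± 0.20 and OCLN at -0.35 ± 0.22, with 0.01 and -0.31 on its other probe sets.

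Proliferation genes were slightly lower. Of 37 DNA replication genes, 27 were below 0, with a median of -0.08 and percentile 0.16. MCM10 differed by -0.49 ± 0.20, with only -0.10 and -0.04 on its other probe sets, E2F1 by -0.56 ± 0.29, with 0.01 on its other probe set, POLE by -0.54 ± 0.25 and PCNA by 0.06 ± 0.17. Without the shared probe sets the median was -0.04 and the percentile 6.17, and with all probe sets averaged -0.05 and 0.25. Of 39 mitotic genes, 26 were below 0, with a median of -0.07 and percentile 0.365, but -0.02 and 1.13 with all probe sets averaged. The kinesin KIF20A at -0.58 ± 0.20 was the only one beyond 2 SD, and CDK1 differed by 0.09 ± 0.17. Ribosome biogenesis genes had a median of -0.10 and percentile 0.13. Their largest member, the RNA polymerase I subunit POLR1A, gave -1.41, -0.35 and 0.43 on its 3 probe sets. CDKN1A, the p53-induced cell cycle inhibitor, differed by 0.21 ± 0.17 and CCND1 by -0.21 ± 0.17. The p53 target list had a median of 0.10 and percentile 97.45, the highest of its settings, which went down to 30.1. The G1 list had a median of 0.10 and percentile 95.3, with a range of 77.3 to 98.1 over the settings.

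Xenobiotic metabolism genes were lower, with 13 of 16 members below 0, a median of -0.14 and percentile 0.09, and -0.23 and 0.06 without the shared probe sets. ALDH1A3 differed by -0.57 ± 0.25 and TIPARP by -0.52 ± 0.20. TIPARP is a target of the aryl hydrocarbon receptor, as are AHRR and CYP1B1, which gave -0.46 ± 0.29 and -0.29 ± 0.17. Both of the latter lay within 2 probe-set SD, and targets of this receptor were not tested as a list. NQO1, another member of the xenobiotic list, differed by only -0.03 ± 0.17. Cholesterol synthesis genes had a median of 0.15 and percentile 99.45, with STARD4 at 0.74 ± 0.29, DHCR7 at 0.42 ± 0.22 (0.19 on its other probe set) and HMGCS1 at -0.29 ± 0.20. Without the shared probe sets their median was -0.041 and the percentile 30.4. The percentile was 95.9 with the floor at the 75th percentile and 94.6 with all probe sets of a gene averaged. The hypoxia list had a median of 0.11 and percentile 98.8, but its members went both ways. SLC2A3, a glucose transporter, was at 0.69 ± 0.22 and EGLN3 at 0.61 ± 0.29 (0.54 on its other probe set), and ANGPTL4 at -0.61 ± 0.25, NDRG1 at -0.52 ± 0.20 and PFKFB3 at -0.49 ± 0.17. The immediate early list likewise had a median of 0.10 and percentile 98.45, with ETV4 at 0.81 ± 0.33, KLF4 at 0.42 ± 0.20, FOSL1 at -0.61 ± 0.25 and DUSP4 at -0.48 ± 0.17. With all probe sets of a gene averaged, the percentiles of these 2 lists were 76.2 and 87.7, and without the shared probe sets 96.3 and 90.3.

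**Figure D2:**
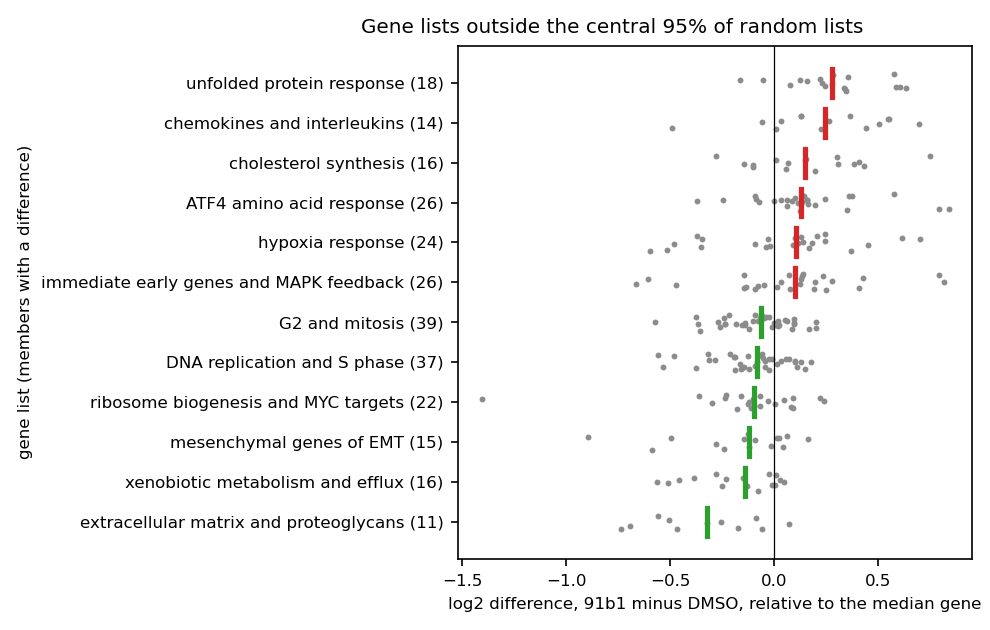
Each row is a gene list, with the number of members having a difference in brackets, and grey points are its members. The x axis is the log2 difference (91b1 minus DMSO) relative to the median gene, and coloured bars mark list medians.

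Lists tied to metal handling did not stand apart. Metallothioneins and zinc or copper transporters, 23 members, had a median of 0.03 and percentile 68.7, with MT1H at -0.37 ± 0.17 and SLC39A8 at 0.28 ± 0.20 (0.74 on its other probe set). The metallothionein genes are near-identical and their probe sets can share targets. Iron handling genes had a median of -0.05 and percentile 12.3, with STEAP3 at -0.44 ± 0.20 (-0.54 on its other probe set) and LCN2, a siderophore-binding protein, at 0.84 ± 0.25. The NRF2 antioxidant list had a median of 0.03 (-0.02 after loess) and percentile 50.3, with GPX2 at 0.31 ± 0.17 (a bound of -0.18 on another probe set) and SLC7A11 at -0.25 ± 0.17 (0.04 and -0.28 on its other probe sets). Several NRF2 members were already high in the DMSO array, with AKR1B10 at 43128, TXN at 42472 and NQO1 at 30815. The maximum of that array was 46984. Others were lower, such as ABCC2 at 1305 and OSGIN1 at 428. Whether signals near the maximum could still rise was not tested. Heat shock genes had a median of 0.07 and percentile 88.3. Autophagy and lysosome genes had a median of 0.05 and percentile 86.1, with TFEB at -1.06 ± 0.33 and NEU1 at 0.95 ± 0.29. The medians of the remaining lists were -0.01 for glycolysis (percentile 22.6), 0.01 for fatty acid synthesis (54.1), 0.04 for oxidative phosphorylation (79.2), 0.05 for apoptosis regulators (78.9), -0.06 for homologous recombination (11.1), -0.01 for EGF family genes (46.0), 0.02 for YAP and TGF-beta targets (51.4), 0.05 for Wnt and Notch targets (75.1) and 0.09 for histones (84.1). Over the settings the percentiles went from 50.1 to 87.8 for metallothioneins and transporters, 8.75 to 36.9 for iron handling, 14.4 to 93.2 for NRF2, 79.9 to 97.0 for heat shock, 74.6 to 92.5 for autophagy, 40.3 to 81.7 for oxidative phosphorylation, 26.5 to 82.6 for apoptosis regulators, 6.24 to 21.5 for homologous recombination and 48.2 to 87.0 for histones. Some lists turned or gained a place in the outer 2.5% under another setting. EGF family genes had a median of 0.0022 with the floor at the 50th percentile, 0.03 after quantile normalization and 0.04 after loess. They had -0.13 with the floor at the 75th percentile and also without the shared probe sets, -0.12 (percentile 3.24) with all probe sets averaged, and -0.27 (percentile 1.32) where the other probe sets of each gene shared its direction. YAP and TGF-beta targets had -0.01 after quantile normalization, -0.0032 after loess and -0.02 with the floor at the 75th percentile. Wnt and Notch targets had 0.16 (percentile 98.99) with the floor at the 50th percentile and -0.02 (42.7) without the shared probe sets. With all probe sets averaged, apoptosis regulators had -0.01, fatty acid synthesis -0.06 and glycolysis 0.0047. Where the other probe sets shared the direction, fatty acid synthesis had -0.03 and glycolysis -0.09 (percentile 2.23). Glycolysis had 0.0071 with the floor at the 50th percentile and 0.00090 with an offset equal to the floor. BMP4, in the TGF-beta list, was higher by 1.03 ± 0.29. EGFR was at -0.47 ± 0.20, with -0.44 and -0.34 on its other probe sets.

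Reference genes were close to 0, with medians of 0.02 for 30 ribosomal proteins (-0.03 after loess; percentile 23.9, and 1.47 with all probe sets averaged) and -0.00066 for 13 common reference genes (percentile 26.8; medians from -0.07 to 0.03 in other settings), although RPLP2 gave -0.67 ± 0.25 and POLR2A -0.66 ± 0.25, and YWHAZ -0.49 ± 0.17 with 0.23, 0.11, 0.46 and 0.01 on its other probe sets. The array's own controls gave a measure of RNA and labelling. The ACTB control differed by 0.50 at its 5' end, 0.15 in the middle and 0.02 at its 3' end, and GAPDH by 0.02, -0.10 and -0.10. After median centring GAPDH turned to 0.18, 0.06 and 0.06, and after loess its 5' end to -0.02 and the 3' end of ACTB to -0.02. The 18S ribosomal RNA control gave -0.38 at its 5' end, -0.32 in the middle and -0.41 at its 3' end. The 18 hybridisation spikes had a median of -0.02 and the 24 labelling spikes a median of 0.05.

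Markers of endothelial cells, fibroblasts and leukocytes were nearly all under the floor on both arrays. This did not hold for a liver-type list chosen after seeing the data. Of its 20 genes, 8 were above the floor on both arrays, as described below. None of 10 endothelial markers, 2 of 10 fibroblast markers (THY1 and COL1A1) and 2 of 13 leukocyte markers (ITGAM and CD14) had a difference or bound, and 4 of 43 genes restricted to other tissues did. Squamous keratin and differentiation genes were also mostly under it. Only 6 of 23 were above the floor, namely SLPI, LCN2, KRT4, CNFN, KRT10 and SOX2 (median -0.11, percentile 13.7). Their median was -0.24 (percentile 2.34) with the floor at the 50th percentile, -0.03 with the floor at the 75th, -0.0017 with all probe sets averaged, and 0.85 without the shared probe sets, where fewer than 5 members were left. The basal keratin KRT5 read 25.8 (DMSO) and 9.55 (91b1), and KRT14 read 2.81 and 1.45. Of the simple epithelial keratins, KRT8 read 22095 and 24656 and KRT18 read 37762 and 36162.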

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

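Outside the named genes, 2 of 2463 probe sets without a single gene symbol that were above the floor on both arrays were at least 2-fold higher in the 91b1 array, and 11 were at least 2-fold lower. Together these were 0.53% of them, against 0.52% of the probe sets with 1 gene symbol.

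Among the array controls, the 5' probe set of ACTB stood 0.50 higher on the log2 scale in the 91b1 array, while its 3' probe set differed by 0.02.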

How the results depend on the processing

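The direction of the 2-fold split and the size of both counts depended on the processing, and the causes were not tested except where the setting itself changes how many genes can count. Against 28 higher and 39 lower genes, the counts were 67 and 15 with each array centred on its median. With the floor at the 50th percentile they were 72 and 138, at the 75th percentile 7 and 3, and at the 90th percentile of genes restricted to other tissues 48 and 79. They were 10 and 20 with an offset equal to the floor, 16 and 12 with all probe sets of a gene averaged, 18 and 25 without probe sets ending in _x_at or _s_at, 243 and 319 at 1.5-fold, and 0 and 0 at 3-fold. Of the 10 and 20 genes with the offset, only 8 and 6 were among the 28 and 39. Quantile normalization (37 and 29), loess (38 and 27), agreement of the other probe sets, the central 95% at like level, and leaving out bounds (the last chosen after seeing the data) kept both counts within 1.5 times. Of CCL5's 3 probe sets, 1 passed the floor when it was set at the 50th percentile. FUT6 turned from a lower to a higher value (0.60) and cholesterol synthesis to a median of -0.041 without the shared probe sets, where another probe set represents the gene. The unfolded protein response stayed between percentiles 99.6 and 100 under these settings, the ATF4 list between 99.4 and 99.99, chemokines between 99.1 and 99.99, extracellular matrix between 0 and 0.49, and xenobiotic metabolism between 0.02 and 0.25. Up to 10 of 35 list medians and 52 of 180 named genes moved under a setting. No paired analysis was possible because each group has 1 array, and for the same reason no replicate could be left out. Signal over background limits the genes near the floor, where the probe-set SD was 0.33.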

Other observations

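The tests on cell identity, the loess median of the unfolded protein response and the means by gene of the 2-fold genes were chosen after the values were seen. All 3 fibrinogen chains were higher in the 91b1 array: FGG by 1.34 ± 0.20, FGB by 1.19 ± 0.17 and FGA by 0.80. Other liver-type secreted proteins above the floor differed less, with complement C3 at 0.40, AMBP at 0.26 and APOH, an apolipoprotein, at 0.13. The urea cycle enzyme CPS1 went the other way at -1.23 ± 0.20, as did the endodermal transcription factor FOXA2 at -0.45, and the regulator ONECUT2 at -0.32, while FOXA3 and FOXA1 were at 0.50 and 0.24. FGA, C3, AMBP, APOH, ONECUT2 and the FOXA genes come from a lineage list chosen after seeing the data. The tetraspanin-like genes TM4SF4 and TM4SF20 were higher by 1.07 ± 0.22 and 1.02 ± 0.22.

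Most squamous genes were under the floor on both arrays. Of 27 named squamous epithelium genes, 7 (25.9%, Wilson 95% interval 13.2% to 44.7%, over genes, which are not independent) were above the floor on both arrays: PERP, SFN, S100A2, JAG2, PITX1, FGFBP1 and CSTA. KRT5, KRT14, DSG3, SERPINB5 and PKP1 were not. With the floor at the 50th percentile, 11 were (40.7%, 24.5% to 59.3%). Of other lineages, 4 of 6 simple epithelium keratins and 8 of 20 liver-type genes (40.0%, 21.9% to 61.3%) were above the floor, as were 1 of 7 lung, 1 of 8 intestinal, 0 of 5 melanocyte, 1 of 5 neuroendocrine, 2 of 6 breast and prostate, and 1 of 5 kidney genes. The 8 liver-type genes were APOH, C3, FGA, AMBP and the regulators FOXA1, FOXA2, FOXA3 and ONECUT2. APOB, APOC3, HP, SERPINA1, SERPINA3 and AFP were not above it. ALB, APOA1 and TTR, held in the list of genes restricted to other tissues, were not either. ALDH1A1 read 31858 and 31945, ALDH3A1 read 17280 and 17224, and CYP24A1 read 12946 and 11760 (DMSO and 91b1).

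As a hypothesis, the RNA on both arrays may come from a cell line other than the one the labels name. The 25.9% of squamous genes above the floor cannot tell this apart from the named line. No array of that line was at hand for comparison, and the interval of the share reaches 59.3% at the lower floor. The intervals of the squamous and liver-type lists also overlap. A minority of other cells, mixed into squamous cells that express these genes, would dilute their signals by less than 2-fold. On the DMSO and treated arrays KRT5 read 25.8 and 9.55, KRT14 2.81 and 1.45, and DSG3 10.8 and 9.27. PKP1 read 15.4 and 1.66, and SERPINB5 22.5 and 3.74. These lie more than 2-fold under the floors of 101.5 and 95.3. They cannot decide on such a mixture, because these genes were picked from the 27 after their values were seen. Their level in unmixed cells of the named line is also not known here. The 7 of 27 squamous genes above the floor do not argue against such a mixture, which stays open. Probe names out of register with the values are argued against by a gap of 95.3 percentage points between ribosomal proteins (100% above the floor) and genes restricted to other tissues (4.65%). Loss of the squamous programme in the named line was not tested and stays open, and SOX2, a squamous lineage gene, read 1852 and 1551.

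The genes at least 2-fold apart were weighed against noise of single probe sets. Of their 12 other probe sets, 83.3% shared the direction (exact 95% interval 51.6% to 97.9%), but these belong to 10 genes and are not independent, and by gene the interval of 44.4% to 97.48% reaches the 50% that noise would give. Averaged by gene, the other probe sets lay 0.72 in the direction of the gene (95% t interval 0.33 to 1.10), which argues against noise as the whole cause for these 10 genes as a set. Over all 2852 genes with exactly 2 probe sets above the floor on both arrays, only 58.5% of pairs shared the direction (r = 0.22 across genes), and 61.2% where the first was at least 1.5-fold apart (134 genes). Noise stays open for the other 38 genes, which have no other probe set above the floor on both arrays. It also stays open for the 6 higher and 13 lower genes past 2-fold as bounds, which were not part of this test.

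The higher unfolded protein response genes were weighed against 3 explanations. A trend of the difference with signal level is argued against, since after a loess fit the list median was 0.27 (95% bootstrap interval over members 0.17 to 0.34) against 0.28 before. Probe sets shared between related transcripts are argued against as the whole cause, since without them the list stayed at percentile 99.6, although its median was then 0.17 (0.08 to 0.34). That setting held 13 members against 18. In the main setting HERPUD1, DNAJB9, PDIA6 and HSP90B1 were each represented by a shared probe set, as were CALR, PDIA4, SEL1L, HYOU1 and SDF2L1. A difference between 2 cultures that is unrelated to the compound cannot be told apart from a response to 91b1, because there is 1 array per group. A difference in RNA or labelling, such as that of the ACTB control (0.50 at its 5' end, 0.02 at its 3' end), was not tested against this list and stays open.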
